A study of Mus musculus with 8 samples.

How the data were processed

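Total RNA was taken from corpus callosum dissected by hand after perfusion, from 4 mice on normal diet and 4 mice after 1 week of 0.25% cuprizone, and 150 ng of each sample was amplified, labelled and hybridised to an Affymetrix Mouse Gene 1.0 ST array, per the labels' protocols. This array carries probes along the whole transcript, which are summarised into transcript clusters. The deposited values are on the log2 scale, and the submitters' processing notes name Expression Console, RMA and the Transcriptome Analysis Console, without versions or a role for each. RMA as published corrects the background, quantile normalizes the arrays and summarises the probes of a cluster. Where arrays are brought to nearly the same distribution, a shift shared by most transcripts cannot be seen, and large folds of bright or dim clusters are compressed. The deposited table held 28944 clusters on 8 arrays, with levels between 2.21 and 14.1. Scanner files, scan dates and detection calls were not used here, so no batch was tested and signal over background is not known per cluster.

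Clusters were named through the platform annotation supplied with the series: 21789 clusters had exactly 1 gene symbol, 1621 had several and 5534 had none. Of the clusters with 1 symbol, 21698 were matched by Entrez identifier to a current RefSeq gene table, and 0 were given a newer symbol. The 23410 clusters with at least 1 symbol were tested, and no gene was named from a cluster with several symbols. Samples were grouped by their labels, which call them biological replicates 1 to 4 of each diet.

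Each cluster was tested with limma (version 3.58.1 in R 4.3.3), by a linear model of the 2 groups with moderated variances at default settings, no covariate and no filter on dim clusters, two-sided. P-values were adjusted by the Benjamini-Hochberg method over the tested clusters, and an adjusted p under 0.05 was the threshold. A second count took clusters that also changed at least 1.5-fold. Errors given after ± beside a log2 fold change are standard errors from that model, and those beside a mean level are SDs over 4 arrays. Wherever the text gives an adjusted p for a gene, it comes from limma.

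Before the data were examined, 38 gene lists were fixed: markers of oligodendrocytes, their progenitors, microglia, astrocytes, vessels, blood leukocytes, neurons, choroid plexus, meninges and red blood cells, and genes of lipid synthesis, stress responses, copper handling, respiration, inflammation, proliferation and ribosomes. For the list tests each gene was represented by its single-symbol cluster with the highest mean over the 8 arrays. Together the lists had 733 different measured genes. Lists with at least 5 measured genes, 37 of them, were tested with camera at its preset correlation between genes of 0.01, adjusted over the lists. Members were counted over all clusters and adjusted over the list alone. The mean of a list's genes per array was compared by an exact two-sided permutation test over the 70 assignments of the arrays, adjusted over the lists.

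The genes named were also set by a rule fixed beforehand. It took the 15 largest increases and the 15 largest decreases among single-symbol clusters past the threshold whose groups did not overlap, without predicted genes, clone names, small RNAs and olfactory or vomeronasal receptors. It took up to 4 members with the smallest p of each list among those past the threshold, or the 2 members with the smallest p where none passed. It also took Mbp, Mog and Mag in any case, together with an item that is not reported here, and for the closing section the list genes that an explanation needs. The rule left 53 clusters unnamed for their symbols, 0 of them beyond the smallest named change. List genes without a single-gene cluster were not analysed here.

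The steps were tested on simulated data with the means and spreads of these arrays. In that simulation of cuprizone against control, over 23410 clusters, 60 of 67 changes of 1.5-fold (89.6%), 67 of 67 changes of 2-fold and 65 of 66 changes of 4-fold (98.5%) were recovered. Of 201 calls 9 were false, a simulation without changes gave 0 calls, and a list shifted on purpose was called with 0 other lists. The simulated clusters were drawn independently of each other and the simulated lists at random. The simulation therefore does not show how often camera calls a list of correlated genes falsely. On the real arrays the estimated correlation was, for example, 0.795 in the interferon response list.

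The alternatives, set at the same time as the lists, were the replicate number as a block, leaving out each array, a trend and robust prior, an ordinary F test, quantile normalization again, centring each array on its median, 2 filters on dim clusters, all clusters with or without a name, 1 cluster per gene, array weights, the mean of the general neuron list as a covariate and a test against a 1.2-fold change. For the lists they were camera with an estimated correlation, fry, the mean of all clusters of a gene and only members above the median level. All 35 splits of the 8 arrays into 4 and 4 were fitted as well. Further values and the plots were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.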

Results

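Transcript levels were measured in the corpus callosum, the large white matter tract that joins the cerebral hemispheres, of male wild-type C57BL/6 mice. Cuprizone is a copper chelator that damages oligodendrocytes when fed to mice, and here it made up 0.25% of the diet for 1 week. The 8 arrays fell into 2 groups of 4 biological replicates, a control group on normal diet and a cuprizone group, all from mice aged 8 weeks per the labels. The median log2 level of the gene-named transcript clusters lay between 7.44 and 7.49 on the 8 arrays. Arrays of the same group correlated at 0.9952 to 0.9971 over these clusters and arrays of different groups at 0.9884 to 0.9944. The first principal component held 52.2% of the variance and separated the groups. Control replicate 2 stood at -13.2 on it, against -18.1 to -18.6 for the other controls, and cuprizone replicate 2 stood at 8.73, against 16.5 to 22.5 for the other cuprizone arrays. The number of arrays limits the precision of every value below.

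The comparison addressed by the design is cuprizone against control diet, and the title of the series places it in the context of oligodendrocyte degeneration and brain inflammation. After 1 week of cuprizone, genes of myelin and of the mature oligodendrocyte were among those that had fallen most, and single chemokine genes, interferon-response genes and genes of stress and glial activation were among those that had risen most. Mog (transcript cluster 10450845), a glycoprotein of the outer myelin surface, fell from 11.14 ± 0.12 to 7.36 ± 0.45 (mean log2 level ± SD, n = 4 each), 13.8-fold lower, with a log2 fold change of -3.78 ± 0.18 (SE, limma adjusted p = 1.14e-06). Mag, a myelin adhesion molecule, was 9.18-fold lower and Mal, a membrane protein of myelin, 8.08-fold lower. Cxcl10 (transcript cluster 10531415), a chemokine that attracts T cells, rose from 6.87 ± 0.73 to 10.46 ± 0.88, 12.1-fold higher, with a log2 fold change of 3.59 ± 0.43 (limma adjusted p = 0.000391).

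Beside Cxcl10, the 15 largest increases by the naming rule held the chemokine Ccl3 (log2 fold change 2.85 ± 0.21), the stress transcription factor Atf3 (2.71 ± 0.36), the matrix protein tenascin C, Tnc (2.68 ± 0.12), the p53-induced receptor Eda2r (2.49 ± 0.29), the transglutaminase Tgm1 (2.47 ± 0.08) and the calcium-binding protein S100a11 (2.11 ± 0.24). Interferon-induced genes made up a further part of them, with Ifit3 at 2.81 ± 0.48, Ifit1 at 2.71 ± 0.46, Ifit3b at 2.46 ± 0.44, Ifi207 at 2.30 ± 0.41, Oasl2 at 2.26 ± 0.43 and Trim30d at 2.17 ± 0.37. Dthd1 rose by 3.22 ± 0.16 and Bpifc by 2.30 ± 0.16. The 15 largest decreases were, after Mog, Mag and Mal, Aspa, the aspartoacylase of oligodendrocytes (-2.83 ± 0.21), Fa2h, which makes the hydroxylated fatty acids of myelin lipids (-2.60 ± 0.12), Tmem88b (-2.48 ± 0.14), Ugt8a, the galactosyltransferase of cerebroside synthesis (-2.21 ± 0.12), Ppp1r14a (-2.19 ± 0.11), Tspan2 (-2.16 ± 0.20), the myelin claudin Cldn11 (-2.15 ± 0.12), Ermn (-2.01 ± 0.19), Opalin (4.01-fold lower), the sphingosine phosphate receptor S1pr5 (-1.93 ± 0.14), Efhd1 (-1.86 ± 0.09) and the protease Klk6 (-1.86 ± 0.06). Oasl2 had a limma adjusted p of 0.00733, and of 0.0567 with an intensity trend and a robust prior, over a range of 3.14e-05 to 0.0880 in the alternatives run.

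**Figure D1:**
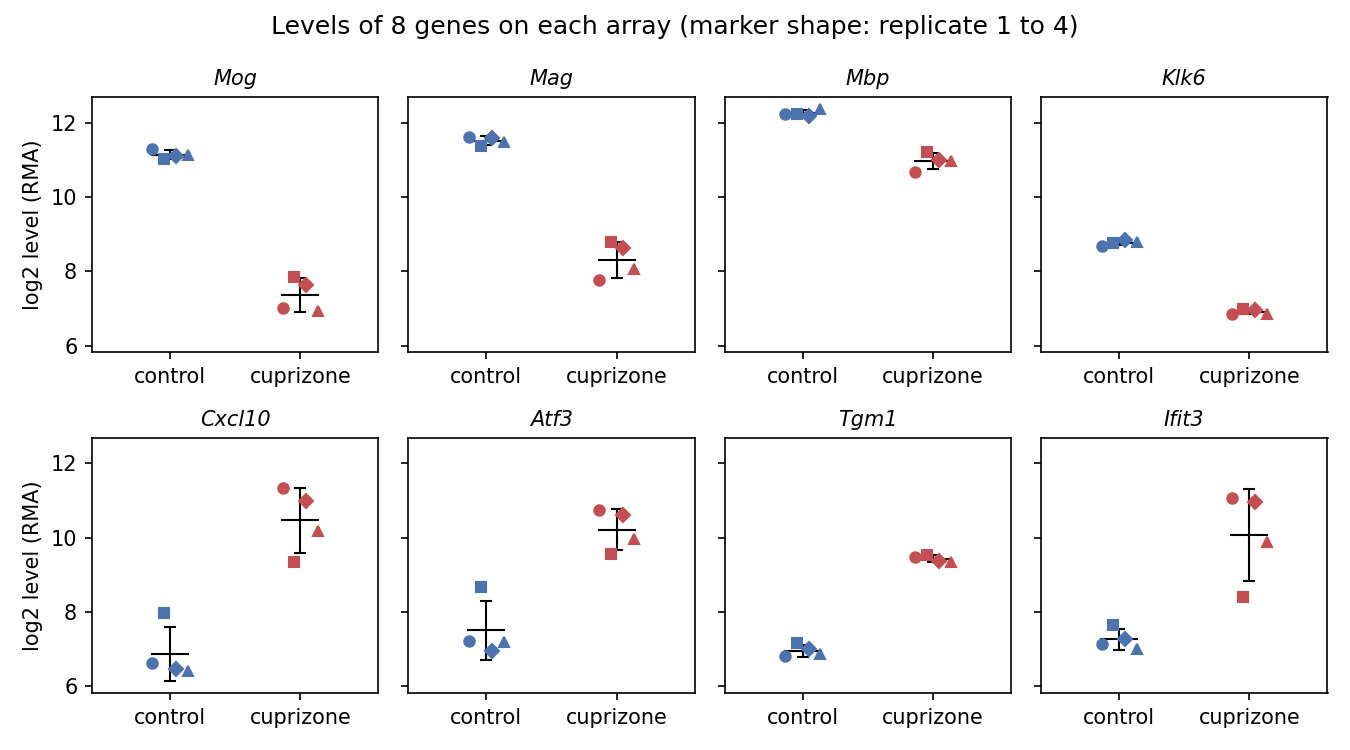
Log2 RMA level (vertical axis) of 8 genes on each array, with control arrays in blue, cuprizone arrays in red, marker shape for the replicate number and black bars for the group mean ± SD (n = 4). Mog, Mag, Mbp and Klk6 lay lower on every cuprizone array than on every control array, and Cxcl10, Atf3, Tgm1 and Ifit3 higher, with control replicate 2 at 7.96 for Cxcl10 and 8.68 for Atf3.

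Of 23410 transcript clusters tested, 1102 were higher and 823 lower with cuprizone at a limma adjusted p under 0.05, and 328 of the higher and 213 of the lower ones changed at least 1.5-fold. At least 2-fold changes were found for 114 higher and 74 lower clusters. Among clusters with exactly 1 gene symbol, those past the threshold at any fold stood for 978 higher and 753 lower genes. No such gene had clusters called in both directions. The groups did not overlap in 15.3% of the clusters tested, where 2.86% would be reached by chance. The counts were 901 higher and 642 lower without control replicate 2, and 1122 higher and 741 lower without cuprizone replicate 2. An ordinary F test without moderation called 632 clusters higher, and 4867 clusters in both directions passed an unadjusted p of 0.05 in limma.

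The list of mature oligodendrocyte and myelin genes fell almost as a whole. Of its 37 measured members 36 fell and none rose, both over all clusters and adjusted over the list alone, and the median log2 fold change was -1.58. Of its members, Klk6, Fa2h, Mog and the axoglial adhesion molecule Cntn2 (-1.30 ± 0.06) had the smallest p in limma. Mbp, which encodes the main cytoplasmic protein of compact myelin, fell 2.43-fold, from 12.24 ± 0.08 to 10.96 ± 0.22. The member past no threshold was the lineage transcription factor Sox10, at -0.14. The mean of the list fell by 1.32 to 1.89 on the log2 scale on the 4 cuprizone arrays, and stood at -0.11 on control replicate 2, against 0.00 to 0.08 on the other controls. Camera called the list lower, with an adjusted p of 0.102 when the correlation between genes was estimated.

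The list of oligodendrocyte progenitors and committed precursors changed less. Of 20 measured members 4 fell and none rose, and adjusted over the list alone 6 fell and 1 rose, with a median of -0.09. The 4 were Enpp6 (-0.75 ± 0.07), a marker of newly forming oligodendrocytes, Rnf122 (-0.70 ± 0.07), Bcas1 (-0.76 ± 0.11), which marks early myelinating cells, and the transcription factor Olig1 (-0.50 ± 0.09). Camera called the list lower (adjusted p = 0.00997), but with an estimated correlation the adjusted p was 0.443. Without cuprizone replicate 1 it was 0.0619 at the preset correlation, and the list median was -0.058. Cholesterol synthesis fell broadly, with 17 of 20 measured enzymes and regulators lower and none higher (20 lower adjusted over the list alone) and a median of -0.44. Examples were the sterol isomerase Ebp (-0.87 ± 0.07), Idi1 (-0.86 ± 0.08), the HMG-CoA synthase Hmgcs1 (-0.75 ± 0.07) and the lanosterol demethylase Cyp51 (-0.65 ± 0.07). In the fatty acid and myelin lipid list 14 of 25 members fell and 2 rose (16 and 3 adjusted over the list alone), with a median of -0.42. Besides Fa2h and Ugt8a, which the mature oligodendrocyte list also holds, the desaturase Scd1 (-0.96 ± 0.09) and the elongase Elovl7 (-1.09 ± 0.11) fell. Camera called both lipid lists lower, with adjusted p of 0.102 for cholesterol synthesis and 0.181 for fatty acids with an estimated correlation.

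Genes of the integrated stress response, which slows translation and induces the transcription factors ATF4 and CHOP, rose. Of 34 measured members 20 rose and 1 fell (22 and 3 adjusted over the list alone), with a median of 0.36. Atf5, itself a transcription factor of this response, rose 2.33-fold (1.22 ± 0.06), the cystine transporter gene Slc7a11 2.47-fold (1.30 ± 0.13), Nupr1 2.43-fold (1.28 ± 0.12) and Cebpg 1.52-fold (0.60 ± 0.05). Among cytosolic aminoacyl-tRNA synthetases 4 of 16 rose and none fell (9 and 0 adjusted over the list alone), led by Eprs (0.73 ± 0.06), with a median of 0.16. Of 20 endoplasmic reticulum chaperone genes 4 rose and none fell, both over all clusters and adjusted over the list alone, with a median of 0.09. Edem1 rose by 0.34 ± 0.05 and Creld2 by 0.42 ± 0.09. Camera called the 3 lists higher. With an estimated correlation the adjusted p was 0.102 for the stress response, 0.311 for the synthetases and 0.463 for the chaperones, and fry gave 0.111 for the chaperones. The list of ribosomal protein genes, taken as a check of RNA quality, had a median of 0.17, about that of the synthetases and above that of the chaperones. Cuprizone replicate 3 stood highest of the arrays on the ribosomal, synthetase and chaperone means, at 0.33, 0.31 and 0.22. Control replicate 2 stood at 0.14 on the mean of the stress response list, against -0.07 to -0.03 for the other controls and 0.39 to 0.55 for the cuprizone arrays.

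Targets of the tumour suppressor p53 and apoptosis genes also rose, in 14 of 21 measured members with none lower (15 and 1 adjusted over the list alone) and a median of 0.44. Gadd45b rose 2.80-fold (1.49 ± 0.11), the cyclin Ccng1 1.92-fold (0.94 ± 0.10), Gadd45a 1.91-fold (0.94 ± 0.10) and Phlda3 1.84-fold (0.88 ± 0.10). Camera called this list higher, with an adjusted p of 0.102 with an estimated correlation, and control replicate 2 stood at 0.16 on its mean, against -0.09 to -0.03 for the other controls. The NRF2 antioxidant list was not called (3 of 20 members higher and 2 lower, also adjusted over the list alone), and had an adjusted p of 0.00583 over its members brighter than the median cluster and of 0.0219 with the neuronal mean as a covariate. The haem oxygenase Hmox1 (1.86 ± 0.27), the epoxide hydrolase Ephx1 (1.35 ± 0.12) and Slc7a11, shared with the stress response list, rose, and Taldo1 fell (-0.39 ± 0.06). In the copper handling list, of interest because cuprizone binds copper, 2 of 17 members rose (3 adjusted over the list alone), the copper-carrying ferroxidase Cp (0.73 ± 0.10) and the copper pump gene Atp7a (0.33 ± 0.08). The adjusted p of Atp7a was 0.0257, and 0.0515 to 0.0765 when any 1 of 5 arrays (control replicate 1, 2 or 3, cuprizone replicate 2 or 4) was left out. Camera called the copper list higher at a median of 0.06, below that of the ribosomal protein genes, with an adjusted p of 0.211 with an estimated correlation. None of 37 nuclear-encoded respiratory chain genes passed the limma threshold over all clusters or adjusted over the list alone, and 0 passed at an unadjusted p under 0.05. The smallest p was that of Ndufa1 at -0.17 ± 0.08 (limma adjusted p = 0.247), and the list was not called, but had an adjusted p of 0.00195 with the neuronal mean as a covariate. The heat shock list was not called (2 of 14 members higher and 1 lower, 3 and 1 adjusted over the list alone), and had an adjusted p of 0.0128 without control replicate 3, of 0.00868 without cuprizone replicate 2 and of 0.000663 with the neuronal mean as a covariate. In it Hspb8 (1.22 ± 0.16) and the co-chaperone Bag3 (0.50 ± 0.09) rose and Cryab, a small heat shock protein abundant in oligodendrocytes, fell (-1.04 ± 0.08).

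Microglial genes rose. Of 22 measured genes of resident microglia 14 rose and none fell (17 and 0 adjusted over the list alone), with a median of 0.46. Ly86 rose 2.26-fold (1.18 ± 0.09), the leukocyte phosphatase Ptprc 1.99-fold (0.99 ± 0.08), Laptm5 1.59-fold (0.67 ± 0.07) and the colony stimulating factor receptor Csf1r 1.53-fold (0.61 ± 0.06). Of 29 genes of activated and phagocytic microglia 18 rose and none fell (23 and 0 adjusted over the list alone), with a median of 0.71. Examples were Cd52 (1.55 ± 0.15), the protease inhibitor Cst7 (1.35 ± 0.13), the glucan receptor Clec7a (1.11 ± 0.10) and the signalling adaptor Tyrobp (0.94 ± 0.08). Of 16 complement genes 7 rose and 1 fell (8 and 2 adjusted over the list alone), with a median of 0.31. The receptor C3ar1 rose 2.44-fold, the recognition subunit C1qb 2.20-fold, C4b 2.13-fold and the integrin subunit Itgb2 1.55-fold. Camera called the 3 lists higher, and with an estimated correlation the adjusted p was 0.169 for resident microglia and 0.102 for the other two lists. Cuprizone replicate 3 stood highest on the 3 means, at 0.63, 0.88 and 0.57, as it did on that of the ribosomal protein genes (0.33).

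Chemokine genes rose in 7 of 25 measured members and fell in 2 (12 and 2 adjusted over the list alone), with a median of 0.16, about that of the ribosomal protein genes, 0.17, and a mean of 0.49. Control replicate 2 stood at 0.11 on the mean, against -0.08 to 0.02 for the other controls. Besides Cxcl10 and Ccl3, Ccl5 rose 2.10-fold (1.07 ± 0.16) and Cxcl16 1.91-fold (0.93 ± 0.11). Camera called the list higher, with an adjusted p of 0.143 with an estimated correlation. Over the members brighter than the median cluster, the list median was 0.05 and camera's adjusted p was 0.0994. The list of other cytokines and growth factors was not called, with 4 of 27 members higher and 3 lower (5 and 3 adjusted over the list alone). Il1a (1.14 ± 0.09) and the CNTF receptor ligand Clcf1 (1.21 ± 0.16) rose, whereas the alarmin Il33, which mature oligodendrocytes and astrocytes produce, fell 2.52-fold (-1.33 ± 0.16) and Il18 fell 1.44-fold (-0.53 ± 0.07).

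Interferon-response genes rose in 16 of 23 measured members and fell in none (20 and 0 adjusted over the list alone), with a median of 1.11. Besides Ifit1 and Ifit3, the antiviral membrane protein gene Ifitm3 rose 3.77-fold (1.92 ± 0.27) and the signalling component Irf9 2.32-fold (1.21 ± 0.22). The size differed between the cuprizone arrays, whose list means lay 1.68, 0.36, 1.66 and 0.95 above the control mean for replicates 1 to 4, while the control arrays lay between -0.06 and 0.06. Cxcl10, counted here with the chemokines, had the same order on these arrays, at 11.32, 9.36, 10.99 and 10.18, and so did Atf3. The choroid plexus and ependyma list had the inverse order on the cuprizone arrays, at -0.47, 0.21, -0.36 and 0.09. The median was 1.37 without cuprizone replicate 2 and 0.92 without cuprizone replicate 1. Antigen presentation genes rose in 6 of 15 members and fell in none (8 and 0 adjusted over the list alone), with a median of 0.26. The MHC class I light chain B2m rose 1.93-fold (0.94 ± 0.12), the peptide transporter Tap1 1.84-fold (0.88 ± 0.15), and the costimulatory genes Cd86 1.80-fold (0.85 ± 0.08) and Cd80 1.43-fold (0.51 ± 0.10). Camera called both lists higher, with adjusted p of 0.211 for interferon and 0.169 for antigen presentation with an estimated correlation.

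**Figure D2:**
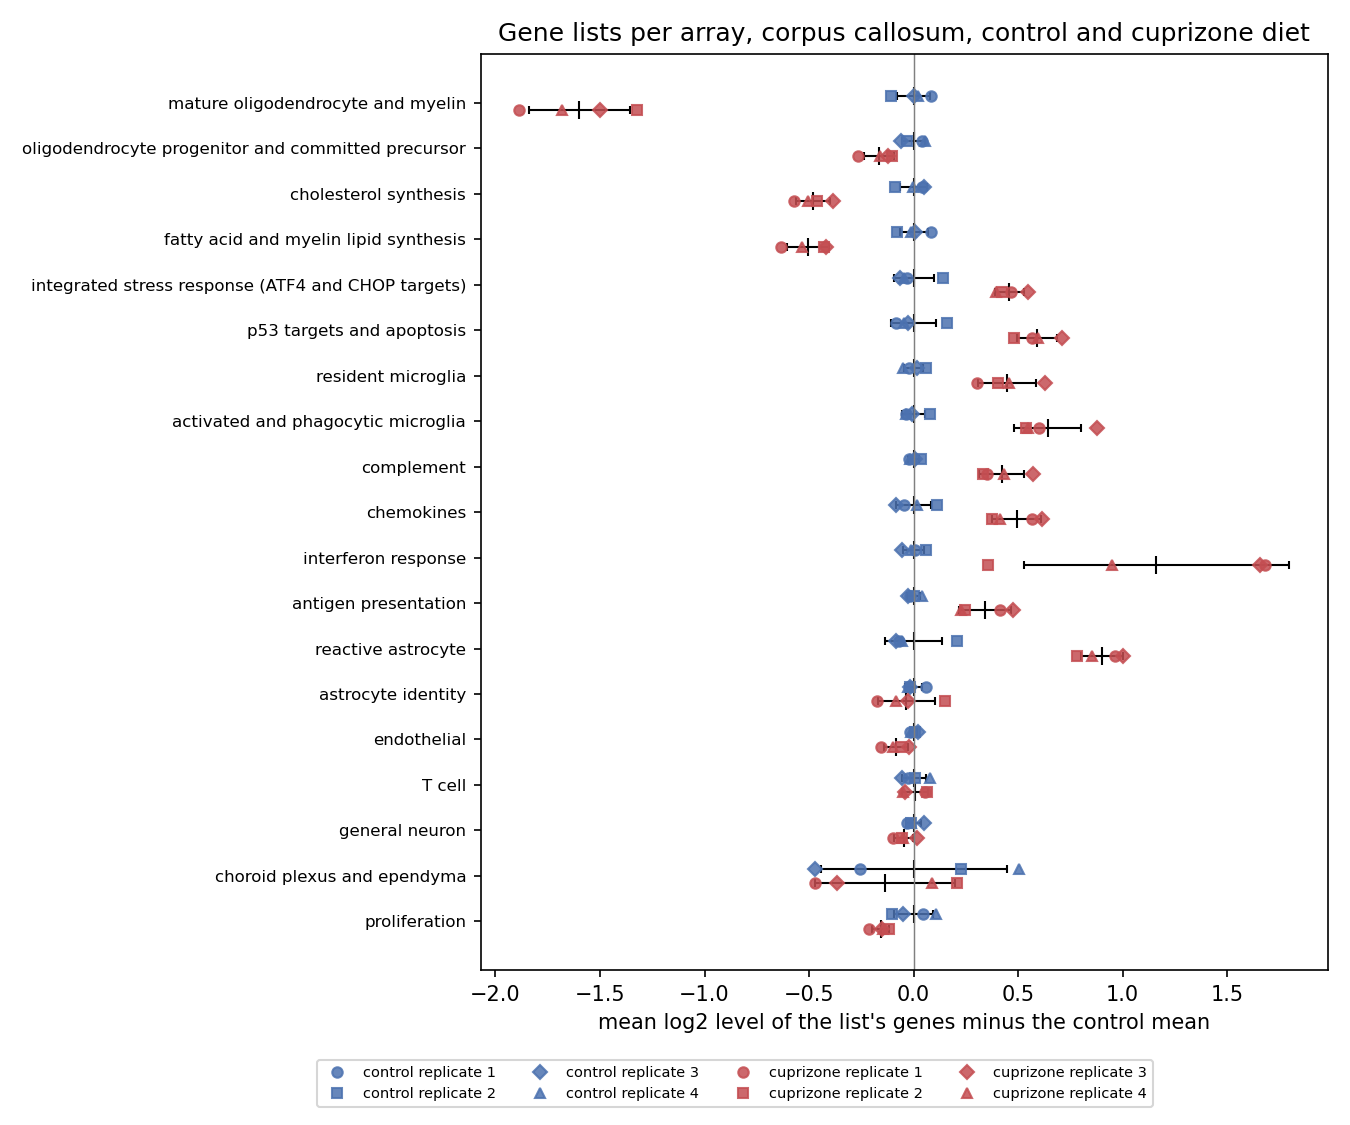
Mean log2 level of the genes of 19 lists on each array, minus the control mean (horizontal axis), with control arrays in blue, cuprizone arrays in red, marker shape for the replicate number and black bars for the group mean ± SD (n = 4). The mature oligodendrocyte list lay 1.32 to 1.89 below the control mean on the cuprizone arrays, the interferon list spread from 0.36 to 1.68 among them, and the choroid plexus list varied from -0.47 to 0.50 among the controls.

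Reactive astrocyte genes rose in 16 of 25 measured members and fell in none (21 and 0 adjusted over the list alone), with a median of 0.82. Serpina3n, a protease inhibitor, rose 3.49-fold (1.80 ± 0.13), the intermediate filament genes Vim 3.33-fold (1.74 ± 0.14) and Gfap 1.95-fold (0.96 ± 0.06), next to Tgm1. Camera called the list higher, with an adjusted p of 0.0843 with an estimated correlation, and control replicate 2 stood at 0.21 on its mean, against -0.08 to -0.05 for the other controls. Genes of astrocyte identity moved both ways, 4 of 22 higher and 5 lower, also adjusted over the list alone, and the list was not called. The urea transporter Slc14a1 (1.19 ± 0.12) and the transcription factor Sox9 (0.43 ± 0.07) rose, while the glutamate transporter Slc1a2 (-0.60 ± 0.07) and glutamine synthetase, Glul (-0.49 ± 0.06), fell. The meningeal fibroblast and extracellular matrix list was not called, at a median of -0.00185 and a mean of 0.16, with 3 of 18 members higher and 1 lower (4 and 2 adjusted over the list alone) and a fry adjusted p of 0.0474. Besides Tnc, fibronectin, Fn1 (0.57 ± 0.05), and Igfbp2 (0.70 ± 0.14) rose and the laminin subunit Lama2 fell (-0.45 ± 0.09).

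Lists of blood-borne and vascular cells showed few called genes. None of 16 T cell genes, 8 B cell genes or 12 border macrophage genes passed the limma threshold over all clusters or adjusted over the list alone. At an unadjusted p under 0.05, 2 T cell genes and 1 B cell gene were higher and 0 border macrophage genes passed. Csf3r, the granulocyte colony stimulating factor receptor, rose by 0.58 ± 0.09, as 1 of 17 genes of blood monocytes and neutrophils to pass, also adjusted over the list alone. The members with the smallest p were Cd247 (0.16 ± 0.06) for T cells, Cd22 (0.19 ± 0.07) for B cells and Lyve1 (0.11 ± 0.06) for border macrophages. The mean of the T cell list differed by 0.0053 ± 0.042 (SE) between the groups, and all of its members were dimmer than the median cluster in the controls. The medians of the T cell, border macrophage and blood monocyte lists were slightly negative and their means positive, and for blood monocytes camera's direction was negative; none of these lists was called, nor was that of B cells. None of 18 endothelial genes passed in limma either way (1 higher and 5 lower at an unadjusted p under 0.05), with Kdr at -0.24 ± 0.07 (adjusted p = 0.0671), and the list, at a median of -0.09, was not called (adjusted p = 0.0657). Without control replicate 1 its adjusted p was 0.0451, without cuprizone replicate 3 it was 0.0172, and after quantile normalization again it was 0.0400. Of 14 leukocyte adhesion genes 2 rose (3 higher and 1 lower adjusted over the list alone), Vcam1 by 0.72 ± 0.08 and F11r by 0.41 ± 0.07, with a list median of -0.03, a mean of 0.05 and a fry adjusted p of 0.0157. Of 14 pericyte and smooth muscle genes 2 rose, also adjusted over the list alone, among them Tagln (0.44 ± 0.08). Camera called neither list. For red blood cells 2 genes were measured, too few for a list test, with Alas2 at 0.03 ± 0.10 and Slc4a1 at -0.02 ± 0.07.

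Neuronal lists moved little. Their mean levels in the controls were 10.76 (general), 10.05 (striatal and septal), 9.67 (cortical and hippocampal) and 9.31 (inhibitory), against 9.82 for mature oligodendrocytes. The samples therefore held neuronal RNA, and changes of glial lists cannot be placed in white matter alone. None of 20 general neuron genes passed in limma over all clusters or adjusted over the list alone (0 higher and 2 lower at an unadjusted p under 0.05), the member with the smallest p being Syn2 (-0.20 ± 0.06), and the list mean differed by -0.048 ± 0.030 (SE) between the groups. That list was not called (adjusted p = 0.199), but without cuprizone replicate 3 its adjusted p was 0.0373. Of 15 cortical and hippocampal excitatory neuron genes 1 fell (0 adjusted over the list alone) at a median of -0.14; this was Rasgrf2 (-0.25 ± 0.07, adjusted p = 0.0498), whose adjusted p was 0.0668 to 0.129 when any 1 array other than control replicate 4 was left out. Camera called that list lower, with an adjusted p of 0.169 with an estimated correlation. The striatal and septal list, with Zic2 higher (0.54 ± 0.10; 1 of 13, also adjusted over the list alone), was not called, and had an adjusted p of 0.0113 without cuprizone replicate 4. The inhibitory neuron list, with Dlx1 lower (-0.21 ± 0.06; 1 of 14, 3 adjusted over the list alone), was not called, and Dlx1 had an adjusted p of 0.0423, and of 0.0563 to 0.115 without any 1 array. Choroid plexus and ependyma genes varied between arrays of both groups, and 1 of 15, Rarres2, fell (-0.34 ± 0.07; also adjusted over the list alone). That list was not called, and had an adjusted p of 0.0234 without control replicate 3.

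Immediate early genes rose in 7 of 20 members and fell in 1, also adjusted over the list alone, with Jun at 0.69 ± 0.07, Klf4 at 0.54 ± 0.10, Egr2 at 0.48 ± 0.09 and Ier3 at 0.38 ± 0.07. Camera called the list higher at a median of 0.07, with an adjusted p of 0.375 with an estimated correlation and of 0.0850 at the preset correlation without control replicate 1, where the median was 0.00572. Proliferation genes fell in 4 of 24 members and rose in none (7 and 0 adjusted over the list alone) at a median of -0.16, with the topoisomerase Top2a at -0.53 ± 0.08, Rrm2 at -0.53 ± 0.10 and the cyclin Ccna2 at -0.41 ± 0.09. Camera called this list lower, with an adjusted p of 0.375 with an estimated correlation. Ribosomal protein genes were higher in 2 of 16 members (10 adjusted over the list alone), with Rps18 at 0.38 ± 0.06, all 16 had positive log2 fold changes, and the list was called higher at a median of 0.17 (adjusted p = 0.211 with an estimated correlation).

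In all, camera at its preset correlation called 14 lists higher and 6 lower of the 37 tested, and with an estimated correlation it called 0 in either direction (8 higher and 2 lower at an unadjusted p under 0.05). At the preset correlation, other splits of the 8 arrays into 4 and 4 gave a median of 11 called lists. Some of these splits keep part of the diet contrast, so that median is not a count under chance alone. Since no called list kept its call with an estimated correlation, a call at the preset setting is weak evidence by itself. In an exact two-sided permutation test on the list means per array, 23 of the 38 lists reached the smallest p that 4 against 4 arrays can give, 0.0286, which is 0.0472 after adjustment over the lists. They included the antioxidant, endothelial, leukocyte adhesion and meningeal lists, which camera did not call. Every list that camera called was among them except the endoplasmic reticulum chaperones (permutation p = 0.114, adjusted p = 0.174). Fry, which asks whether a list's genes move one way on balance, called 15 lists higher and 6 lower.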

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

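All tests of explanations below were chosen after the results they bear on had been seen. In groups of 4 arrays, 1 array was counted as apart when its gap to the nearest other array, divided by the range of the group, exceeded Dixon's critical value for 4 values, which chance gives in about 1 of 20 groups. This held in 14 of 266 groups over the named genes and 3 of 76 over the list means, where chance would give 13.3 and 3.8, so their number is close to what chance gives. In 9 of these 17 groups, however, the array apart was control replicate 2.

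Control replicate 2 was apart and highest among the controls for Cxcl10 (gap over range 0.852), Atf3 (0.854), Eda2r (0.963), Ifi207 (0.877), Tap1 (0.947), Cd80 (0.849), the integrated stress response list (0.846) and the reactive astrocyte list (0.901), and apart and lowest for Ugt8a (0.835). Its Atf3 level was 8.68, against 6.96 to 7.21 in the other controls, and its Eda2r level 6.22, against 4.98 to 5.03. It was the control nearest to the cuprizone arrays in 80 of the 107 single-gene clusters that rose at least 2-fold and in 57 of the 74 that fell at least 2-fold. Its median distance from the other controls was 0.24 and -0.18 on the log2 scale.

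One candidate explanation is cuprizone RNA mixed into control replicate 2. One share of cuprizone RNA for all increases and one for all decreases left residuals with an SD at most 1.08 times the highest among the other controls, so a mixture is not excluded by that spread. The shares implied were 0.0911 (quartiles 0.0374 to 0.159) for the increases and 0.187 (0.123 to 0.248) for the decreases, and single genes went from -0.0197 for Dthd1 and 0.00264 for Bpifc over 0.0429 for Tnc and 0.0441 for Tgm1 to 0.243 for Atf3 and 0.263 for Hmox1. The shares of Dthd1, Bpifc, Tnc and Tgm1, single genes picked from the increases, lay below the medians that a mixture would give. Over the increases and decreases as sets, a mixture cannot be told apart from other differences between control animals, since a milder form of the same changes would give the same shares. For the increases the other controls lay at -0.0251 to -0.0405, and for the decreases control replicate 1 lay nearly as far the other way (-0.176). Handling before collection also stays open, since the immediate early list of control replicate 2 was 0.0263 above the highest other control, too close to decide, and no biological explanation was tested.

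Of the remaining arrays apart, Bpifc was lowest in control replicate 3 (0.840) and Rars in control replicate 4 (0.836), and the astrocyte identity list was highest in control replicate 1 (0.867). Among cuprizone arrays, replicate 3 was highest for Rars (0.860), Gadd45a (0.875), Ly86 (0.947) and Bag3 (0.905), and replicate 2 was highest for Gadd45b (0.843).

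The interferon response list spread widely among the cuprizone arrays, with an SD of 0.634 of the list mean, against 0.0492 among the controls. Array-wide scaling or quality would spread other genes alike, but over 10000 random lists of the same size and mean expression the highest SD among the cuprizone arrays was 0.124. Random lists average out unrelated genes, and other fixed lists also spread more than this, among them choroid plexus (SD 0.333) and mature oligodendrocytes (0.241). The comparison therefore argues against a shift shared by all genes, and not against a quality difference that affects certain sets of genes. Control RNA in cuprizone replicate 2, the array with the smallest rise, is argued against as the whole source by the decreases of at least 2-fold, which imply a median control share of 0.0987 (upper quartile 0.149), while the 11 interferon genes that rose at least 2-fold imply 0.864 (lower quartile 0.824) and the 96 other increases of that size 0.403 (quartiles 0.191 to 0.579). The 96 others still include interferon-induced genes outside the list, such as Ifit3b and Ifi207. Different amounts of choroid plexus and ependyma were considered as well. Over cuprizone replicates 1 to 4 that list (15 genes, 0 in another list, with Ttr at a mean of 11.01) stood at -0.47, 0.21, -0.36 and 0.09. This is the inverse order of the interferon list, which 4 arrays cannot set apart from chance (2 of 24 orders are as close, a share of 0.0833 and the smallest possible). Dilution by such tissue would also lower neuronal transcripts, but the general neuron list stood at -0.10, -0.05, 0.01 and -0.05 on these arrays. That argues against dilution as the source of a difference of this size, while other links to the dissection stay open. A difference between animals in the timing or strength of the response is also open, as a hypothesis found and examined on the same arrays. Cuprizone replicate 2 was the cuprizone array nearest to the controls in 81 of the 107 increases, which include interferon genes. It was also nearest in 50 of the 74 decreases, so its position was not confined to interferon genes.

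The fall of the mature oligodendrocyte list may reflect fewer or impaired oligodendrocytes under cuprizone, which is a hypothesis. Less white matter in the cuprizone dissections could raise neuronal transcripts, and no rise was seen. The upper bound of the difference of the general neuron list (2 SE above it) was 0.0112. Its most abundant genes Vsnl1 and Snap25 differed by -0.04 ± 0.06 and 0.02 ± 0.06 between the groups. In the controls, however, these 2 genes already stood at 12.97 and 12.82, above Mbp at 12.24. With neuronal RNA that abundant, less white matter might raise it only slightly, so the comparison does not exclude this explanation. The cortical and hippocampal neuron list, of lower level, differed by -0.13 ± 0.03. All 20 measured genes of the general neuron list lay above the median cluster in the controls, and 0 of them are in another list. An equal loss of every transcript, as from fewer cells alone, cannot be told apart from a change of expression within the cells: the SD of the members' log2 fold changes was 6.61 times their median SE, from -3.78 for Mog to -0.14 for Sox10, but compression on the array and expression in other cell types also give such a spread.

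Other splits of the 8 arrays tested whether chance can give these counts. Of 35 splits into 4 and 4, 1, the real one, gave 1925 or more clusters past the threshold, and the highest other split gave 3. At 1.5-fold the real split gave 541 clusters, the highest other 3, and again 1 of 35 reached the real count. No other split came near either count, but 1 of 35 is the smallest share that these splits can give. The other splits also mix the 2 groups, which widens the spread within each side. The splits alone therefore do not exclude chance for either count. For the lists called by camera at its preset correlation, 5 of 35 splits gave 20 or more, and the highest other split gave 22. The median of the other splits was 11 called lists. The split with 22 set 3 controls and cuprizone replicate 2 against the other 4 arrays. Such a split keeps part of the diet contrast, so the counts of the other splits are not those of chance alone. Chance is not excluded as the source of that number of calls, but these splits cannot show it to be the source either.

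Outside the reported comparison, 138 of the 5534 transcript clusters without a gene symbol passed the threshold in a fit over all clusters, 85 of them higher and 53 lower with cuprizone.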

How the results depend on the processing

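No alternative was added after the results were seen. None of the 24 settings reversed a called result. Of 119 named genes past the threshold, 77 kept the call in every setting in which they were tested. The most calls were lost against a 1.2-fold limit (34) and in the ordinary F test (28), and 0 with quantile normalization again. Leaving out 1 array gave 795 to 1122 clusters higher and 609 to 741 lower, at 1.5-fold 262 to 379 higher and 196 to 232 lower, and 13 to 15 lists higher and 5 to 8 lower. It ended the call of 9 named genes (Atp7a, Cald1, Dlx1, Dnajb9, Dnajc3, Kif11, Rasgrf2, Rplp0 and Wars), at adjusted p of 0.0515 to 0.129. The ordinary F test gave 632 clusters higher and, at 1.5-fold, 212 higher. Clusters above the median level gave 185 higher at 1.5-fold, and those above the upper quartile 565 higher and 483 lower, at 1.5-fold 62 and 91, where fewer clusters were tested. The test against 1.2-fold, a stricter limit, gave 231 higher and 198 lower. Camera with an estimated correlation called 0 lists higher and 0 lower. The F test differed from the reported test only in leaving out the moderation of variances. This camera setting differed only in the correlation, estimated at 0.0576 to 0.795 in the called lists against the preset 0.01. Centring the arrays on their medians moved the median of all clusters from -0.00742 to -0.0287 and the share of higher calls from 57.2% to 50.1%. The labels state no pairing of same-numbered samples. Deviations of same-numbered arrays correlated at -0.186, -0.0246, 0.210 and -0.0646, which gave no evidence of pairing but cannot exclude it. With the replicate block 892 clusters were higher and 636 lower (835 and 600 of them shared with the reported calls), at 1.5-fold 319 and 212, with 15 lists higher and 8 lower; Lars, Rasgrf2 and Dlx1 lost the call. Among lists that were not called, the block gave adjusted p of 0.0434 for endothelial, 0.0259 for choroid plexus and 0.0364 for heat shock genes. Heat shock also passed without control replicate 3 (0.0128) and without cuprizone replicate 2 (0.00868). Every called list lost its call with an estimated correlation, at adjusted p of 0.0843 to 0.463. For lists whose call another alternative changed, the adjusted p over all alternatives ran from 0.00332 to 0.443 for oligodendrocyte progenitors, 0.00148 to 0.375 for immediate early genes, 1.03e-06 to 0.143 for chemokines, 1.17e-05 to 0.463 for chaperones, 0.0172 to 0.452 for endothelial, 0.0234 to 0.925 for choroid plexus, 0.000663 to 0.612 for heat shock, 0.0373 to 0.891 for general neuron, 0.0113 to 0.716 for striatal, 0.00583 to 0.611 for antioxidant, 0.00195 to 0.948 for respiratory chain, 0.0157 to 0.904 for adhesion and 0.0474 to 0.847 for meningeal genes. Signal over background is not known for these values, and dim lists such as that of T cells limit what could be detected.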

Other observations

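The gene families here were chosen after their values were seen, from a larger number looked over, each with the members measured under the symbols chosen for it. The directions given held after centring on the median and after quantile normalization again, with the exceptions named. All 4 measured Fc gamma receptors rose, with Fcgr3 2.13-fold (1.09 ± 0.12), Fcgr4 1.98-fold, Fcgr2b 1.96-fold and Fcgr1 1.77-fold higher, and 1 of the 4 is in a fixed list. Of 10 Toll-like receptors 5 rose and none fell, led by Tlr7 (0.79 ± 0.15) and Tlr13 (0.70 ± 0.08). Of 20 cathepsins 7 rose, with Ctss (1.28 ± 0.17) and Ctsc (1.12 ± 0.11) highest, and Ctsk fell (-0.32 ± 0.08), while Ctsb lost the call after centring (adjusted p = 0.0556). Interferon-inducible GTPases of the guanylate-binding and immunity-related families rose in 7 of 10 members (Gbp2b passed too after quantile normalization again, adjusted p = 0.0199), among them Irgm1 (1.69 ± 0.31) and Gbp3 (1.49 ± 0.28). Of 21 genes of gp130 cytokines and receptors, STAT and SOCS proteins, which include no JAK kinase, 6 rose and none fell in limma. Among them were the oncostatin M receptor Osmr, 3.88-fold (1.96 ± 0.17), its signal transducer Stat3, 1.76-fold (0.82 ± 0.08), and Clcf1. Osmr, Stat3 and Clcf1 are already in fixed lists, as are in all 7 of these 21 genes, 3 of the 10 GTPases and 4 of the 20 cathepsins. Single transcription factor genes outside the lists, picked because they rose, were Runx1 (1.69 ± 0.21), Tfap2a (1.68 ± 0.11), Myc (1.30 ± 0.15), Klf6 (0.92 ± 0.13) and Nfe2l2, which encodes NRF2 and rose from a mean of 8.91 to 10.11.

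Receptor families split by member. Of 10 receptors for sphingosine phosphate and lysophosphatidic acid, S1pr5 (-1.93 ± 0.14) and Lpar1 (-1.36 ± 0.08) fell, while S1pr3 (0.58 ± 0.06), Lpar4 (0.64 ± 0.09) and Lpar6 (0.63 ± 0.11) rose. Of 14 EGF family ligands and receptors the neuregulin receptor Erbb3 fell 2.68-fold (-1.42 ± 0.09), while the ligands Hbegf (1.06 ± 0.13) and Btc (0.87 ± 0.09) and the receptor Egfr (0.43 ± 0.06) rose. Among 29 semaphorins and plexins 5 fell, led by Plxnb3 (-1.30 ± 0.06) and Sema4d (-0.68 ± 0.07), and Plxnb2 (0.63 ± 0.08) and Sema3c (0.42 ± 0.11) rose. After centring, Plxna3, Sema4c and Sema7a passed as lower as well (adjusted p of 0.0472, 0.0472 and 0.0495), and after quantile normalization again Plxna3 and Sema4c did (0.0389 and 0.0434). Of 21 ephrins and Eph receptors 3 fell and none rose in limma, with the ephrin Efnb3 at -1.21 ± 0.09, Epha4 at -0.22 ± 0.06 and Ephb1 at -0.25 ± 0.07. Both enzymes of creatine synthesis fell, Gamt 3.44-fold (-1.78 ± 0.08) and Gatm 1.84-fold (-0.88 ± 0.11), whereas the creatine transporter and kinases measured did not pass the threshold. Other decreases outside the lists were the arginine deiminase Padi2, which citrullinates myelin basic protein (-1.64 ± 0.09), Galnt6 (-1.48 ± 0.11), Septin4 (-1.43 ± 0.10), Qdpr (-1.37 ± 0.12), the netrin receptor Unc5b (-1.37 ± 0.09), the carnosine synthase Carns1 (-1.26 ± 0.08) and the prostaglandin D synthase Ptgds (-1.05 ± 0.18). The adjusted p of these named decreases ran up to 0.00460, for Ptgds.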
